A study of Mus musculus with 3 samples.

How the data were processed

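RNA of single cells from whole mouse embryos at embryonic day 4.5 was measured on a microwell cartridge with barcoded capture beads (BD Rhapsody whole transcriptome kit). There was 1 library of control embryos and 2 libraries of embryos labelled as a maternal and zygotic Sox2 knockout (KO), called KO replicate 1 and KO replicate 2 as the labels number them. The files are sparse matrices of genes by barcodes, 1 per library. Their deposited values are raw expected counts, that is, estimated molecule counts per gene and barcode, without normalization. Between 16.1% and 24.0% of the entries were not whole numbers (tolerance 0.001), as when reads shared between genes are split. The processing notes name STAR 2.7.10a and the mouse genome GRCm39 (mm39) without further settings. The counter's settings and the annotation release are not stated, so no coordinates are given. Genes carry a symbol and a versioned identifier in the files, and 1 of the 55358 features is eGFP, a reporter of the Sox2 construct. Every possible barcode of the bead type is listed, 912673 for the control library and 56623104 for each KO library. The bead version therefore differs between control and KO, and its effect on any difference between the genotypes cannot be told apart from that of the genotype.

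Values were rounded to whole counts, and a gene was detected in a barcode with a rounded count of at least 1. A barcode was called a cell with at least 500 detected genes and at most 25% of its counts from mitochondrial genes. This left 283 control cells, 11 cells of KO replicate 1 and 98 of KO replicate 2, after the mitochondrial limit had removed 10, 5 and 29 barcodes. Doublets were scored with scrublet in the control library and KO replicate 2, which gave 6 and 8, and were kept. KO replicate 1 had too few cells for it. Barcodes with 1 to 9 counts served as a measure of free RNA. From the level of Prl3d1, Prl3d2 and Prl7a1 in the named cells of KO replicate 2 over that in these barcodes, free RNA made up between 4.22% and 10.1% of the counts of those cells. The highest of the 3 shares in a class was used to give the count that free RNA would add to each gene, and the lowest as an alternative. Where this count was subtracted, it was taken from KO replicate 2 only. Its total and the control counts were left as they were, so subtraction can only lower a ratio.

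Cells of all libraries were clustered together in scanpy 1.11.5 (Python 3.11.15, leidenalg 0.10.2). Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes within libraries, 20 principal components, 15 neighbours, a Leiden resolution of 0.5 and seed 0 were used. Sox2, Pou5f1, mitochondrial and ribosomal protein genes and all core, naive and formative pluripotency genes were kept out of the variable genes. Clusters were named epiblast-like (EPI-like), primitive endoderm-like (PrE-like) or trophectoderm-like (TE-like) from fixed marker lists. These share many genes with the pluripotency, primitive endoderm and trophectoderm lists compared below. The EPI markers include Sox2, Utf1, Fgf4, Klf2, Nanog and Pou5f1. Cluster names and each cell's marker level are thus not independent of the genes compared. A cluster was left unnamed when its median depth, relative to its own library, was under that library's median by a factor of more than 3. A cluster led by prolactin genes and found in KO replicate 2 only was kept apart as Prl3d1-positive.

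The comparisons, gene lists, marker lists and the rule for named genes were fixed before the data were examined. A class was to be tested only where every library held at least 10 of its cells. KO replicate 1 held 1 EPI-like and 3 TE-like cells, and no cluster was PrE-like, so the EPI-like, PrE-like and TE-like comparisons and the difference between EPI-like and TE-like cells have no test. For these, counts were summed over the cells of a class, scaled by TMM (edgeR 4.0.16, R 4.3.3), and the control was compared with KO replicate 2, 1 library each. Log2 ratios carry a pseudocount of 0.5 counts. Their 95% intervals come from exact conditional binomial limits and those of levels from exact Poisson limits. Intervals cover counting error only, not the variation between embryos, cells or libraries. A count of 0 is taken to allow up to 3 counts, and a ratio against 0 is given as a bound from it. Genes entered with at least 10 counts in a library and 15 in total. Each list's median was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. On simulated counts, 96.5% of the intervals held the true ratio, a list changed by a log2 ratio of 2 had a recovered median of 1.99, and 0 of 40 unchanged lists left the middle 95% of the random lists.

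All called cells of each library were also summed and tested for KO against control, 1 against 2 libraries, with the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. This leaves 1 residual degree of freedom and assumes that the lone control varies like the KO libraries. The test was run on simulated counts with 200 changed genes, drawn from those with at least 200 counts. Recovery of genes with fewer counts was not simulated. At a biological coefficient of variation of 0.2 it recovered 86% of the 8-fold changes with 60 false calls. It recovered 46% of the 4-fold rises, 8% of the 2-fold rises and 16% of the 2-fold falls there. At 0.5 it recovered 4% with 271 false calls. Other quasi-dispersion settings of edgeR (bias-adjusted, robust, both) were tried after the default's result had been seen. The bias-adjusted setting was held as the main one for a time, and then the default fixed at the start was restored. The bias-adjusted settings made 0 false calls and recovered 0% of the 8-fold changes in both simulations. The default thus found most 8-fold changes at 0.2, though with false calls, and hardly any at 0.5. Which value is nearer to these libraries was not determined, so neither choice can be relied on to separate changed from unchanged genes.

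Sox2 and Pou5f1 were named in every class. From each list, up to 3 members with the largest difference were named, among those past the threshold or, in a class without a test, at least 2-fold different. Where none qualified, the 2 members with the highest mean expression were named. The 10 largest differences in each direction with at least 50 counts were added, without predicted gene models, mitochondrial, ribosomal protein and pseudogenes. The rule asked for the same direction in both KO libraries, which in the classes was read from KO replicate 2 alone since KO replicate 1 has 1 EPI-like cell. Other members of the lists are named as examples after their values were seen. The lists were core, naive and formative pluripotency, primitive endoderm, trophectoderm, FGF/ERK response, WNT targets, polarity and adhesion, basement membrane, glycolysis, oxidative phosphorylation, cholesterol and lipid synthesis, p53 and apoptosis, G2/M cell cycle, dissociation stress, genes of the early zygote, imprinted genes, blood and immune genes, and genes of the maternal tract.

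Alternative settings fixed at the start were RLE size factors, no filter on low counts, DESeq2 1.42.0, at least 1000 or 250 genes per cell, no mitochondrial limit, doublets removed, thinning to equal totals, separate clustering of each library, classes by each cell's marker level, and each KO library left out. Added after the data had been seen were the edgeR settings above, and the leaving out of the Prl3d1-positive cluster, of mitochondrial genes, of cells scoring highest for other lineages and of the largest cell of each library, then the subtraction of expected free RNA at its highest and lowest share, other cell limits for the share of the Prl3d1-positive cluster, and the larger TE-like cluster alone. Several choices were also made after a look at the data: the barcodes of 1 to 9 counts, the prolactin genes as the measure of free RNA, the unnamed low-depth clusters and the separate prolactin cluster. Finer clustering was looked at as well and not used.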

Results

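The data were single-cell RNA profiles of whole mouse embryos at embryonic day 4.5 (E4.5), the late blastocyst. Embryos were flushed at E2.5, cultured for 48 h in KSOM medium and dissociated, with about 13 blastocysts per replicate. There was 1 library of control embryos and 2 libraries of embryos labelled as a maternal and zygotic Sox2 knockout (KO). The genotype label of the control is Oct4fl/Sox2fl, Control, which names Oct4 (Pou5f1) as well as Sox2. The control library held 5313290 counts, KO replicate 1 held 225286 and KO replicate 2 held 3407965. Called cells numbered 283, 11 and 98, with median depths of 6954, 3026 and 4272.5 counts and 2723, 1252 and 1711 detected genes. Cells held 90.4% of the counts in the control library, 16.7% in KO replicate 1 and 76.0% in KO replicate 2. The median mitochondrial share was 8.25%, 14.3% and 5.24%. Within the cell classes 1 control library was compared with 1 KO library, without replicates.

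Sox2, the transcription factor targeted in the KO embryos, was lower in the EPI-like cells of KO replicate 2. Of its 249 counts in all control cells, 239 lay in EPI-like cells, which are among the deepest. An unnamed low-depth cluster of control cells held Sox2 too, at a level given under other observations. Sox2 (ENSMUSG00000074637.8) had 239 of 2164586 counts in the EPI-like cells of the control and 22 of 1368157 in those of KO replicate 2. The levels were 111 CPM (counts scaled to a library of 1e+06; 97.0 to 126) and 16.1 CPM (10.1 to 24.3), a log2 ratio of -2.75 (-3.48 to -2.15). Free RNA would give 0.248 to 0.553 of the 22 counts, so Sox2 reads were left in these cells beyond it. The 11 of these cells that scored highest for EPI markers held 7 of the 22 counts. The rest lay in cells of the class scoring highest for other lineages. Among cells scoring highest for EPI markers the control held 238 counts, a log2 ratio of -3.51 (-4.94 to -2.54). Sox2 is itself one of those markers. Of the 17 EPI-like cells of KO replicate 2, 8 held a Sox2 count, against 40 of 59 in the control, at median depths of 81407 and 36481 counts. TE-like cells, which should lack Sox2, held 0 counts in all 3 libraries, with upper limits of 1.51 CPM in the control and 6.18 CPM in KO replicate 2. In KO replicate 1 the 11 cells held 2 Sox2 counts, both in the single EPI-like cell, or 53.3 CPM (6.45 to 192) against 51.8 CPM (45.6 to 58.7) over all control cells, so a loss was not detectable at this depth. The reporter eGFP had 0 counts in the whole control library and 1510 counts in the EPI-like cells of KO replicate 2, at least 794-fold higher there than the limit set by 3 counts in the control. It was found in 15 of these 17 cells, among them all 8 with Sox2, and in 5 of the 11 cells of KO replicate 1. TE-like cells of KO replicate 2 held 26 eGFP counts, 43.6 CPM, against 336 CPM in barcodes of 1 to 9 counts. Free RNA made up at most 10.1% of the counts of these cells, so a level below that of the barcodes does not show the reporter absent.

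The question of how many embryonic cells each genotype held was addressed by the share of EPI-like cells. They made up 20.8% of the control cells (59 of 283; exact binomial 95% interval 16.3 to 26.1), 9.09% of KO replicate 1 (1 of 11; 0.230 to 41.3) and 17.3% of KO replicate 2 (17 of 98; 10.4 to 26.3). TE-like cells made up 39.2%, 27.3% and 14.3%, or 69.3%, 27.3% and 78.6% with classes by each cell's marker level, where the prolactin cluster described below counts as TE-like. No cluster was PrE-like: cells scoring highest for PrE markers fell in other clusters. The EPI-like cluster (score 0.540 for EPI and 0.274 for PrE markers) held 50 EPI-scoring, 4 PrE-scoring and 5 TE-scoring control cells and 11, 3 and 3 cells of KO replicate 2. It was therefore not made up of EPI-scoring cells alone. EPI-scoring cells held 1904339 of its 2164586 counts in the control, but 694209 of 1368157 in KO replicate 2. Without doublets, 2067614 and 848023 counts were left. Cells scoring for other lineages thus weighed more in the class sum of KO replicate 2 than in that of the control. With each library clustered separately, all 17 EPI-like cells of KO replicate 2 lay in a cluster named PrE-like (score 0.391 for PrE and 0.279 for EPI markers). The control cluster that held 53 of the 59 EPI-like control cells kept the EPI name (0.521 and 0.287). However, Pdgfra, Lamb1, Lamc1, Col4a1, Sox17 and Gata4, genes of primitive endoderm, were among its 10 leading genes. With cells of at least 1000 genes, a PrE-like cluster of 7 control cells, 1 of KO replicate 1 and 3 of KO replicate 2 came apart. KO replicate 2 alone had a cluster of 46 cells led by Prl3d1, Prl3d2 and Prl7a1, placental hormones of the prolactin family. This cluster was 46.9% of the cells of KO replicate 2 (36.8 to 57.3), 30.3% (20 of 66) with cells of at least 1000 genes and 24.4% (31 of 127) without the mitochondrial limit. With at least 250 genes it was 45.7% (84 of 184), and took in 3 of 18 cells of KO replicate 1 and 1 of 360 control cells. Outside this cluster the EPI-like share of KO replicate 2 was 32.7% (17 of 52; 20.3 to 47.1), above the 20.8% of the control. Of the cells in named clusters outside it, the share was 54.8% (36.0 to 72.7) against 34.7% (27.6 to 42.4) in the control. The mean KO share minus the control share was -7.63 points, and 1 against 2 libraries cannot give an exact permutation p below 1/3, so no difference was shown. The sign turned with cells of at least 1000 genes (14.6 points), at least 250 genes (17.2 points) and classes by each cell's marker level (4.55 points). This came from KO replicate 1 alone, with 4 of 6, 13 of 18 and 5 of 11 cells EPI-like. With the prolactin cells counted, KO replicate 2 stayed below the control in these settings, at 24.2% against 30.8%, 24.5% against 31.1% and 17.3% against 26.9%.

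What loss of Sox2 does to the embryonic lineage was addressed in the EPI-like cells, 59 of the control and 17 of KO replicate 2. Most pluripotency genes were lower in KO replicate 2, while Pou5f1 and Nanog were not. Of the 12 core pluripotency genes, 8 were lower and 4 higher, with a median log2 ratio of -1.17, below all 10000 random lists. Sox2, the targeted gene, is a member of this list, at -2.75. It counts among the 8 lower genes and in the median, which was not taken without it. Utf1 (ENSMUSG00000047751.10), a chromatin-bound factor of pluripotent cells, had 583 counts in the control and 26 in KO replicate 2, a log2 ratio of -3.80 (-4.46 to -3.26). Fgf4, the growth factor the epiblast sends to the primitive endoderm, was at -3.02 (-5.10 to -1.74), with 57 and 4 counts. Tdgf1, a co-receptor of NODAL, was at -1.73 and Dppa4 at -1.78. Pou5f1 (ENSMUSG00000024406.17), which encodes OCT4, was 293 CPM in the control and 431 CPM in KO replicate 2, a log2 ratio of 0.56 (0.39 to 0.72). Nanog was at 0.31 (0.16 to 0.46), Sall4 at 0.50 and Lin28a at 0.46.

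Naive pluripotency genes were lower as a group, with 18 of 23 lower and a median of -0.82, below all 10000 random lists. Spic had a log2 ratio of -2.94 (-3.89 to -2.20) and Klf2 one of -2.39 (-3.13 to -1.78). Pecam1 was at -2.58, and free RNA, over the lowest to the highest share estimated for it, would give 9.93 to 22.1 counts of the 18 in KO replicate 2. Where expected free RNA is given below, it is such a range. Klf4 was at -1.03, Esrrb at -0.96, Zfp57 at -1.80 and Dppa3 at -1.36, while Klf5 at 1.06 and Stat3 at 0.74 were higher. Formative and primed genes split, 7 lower and 5 higher of 12, with a median of -1.45, or -1.40 with genes at 0 set at their bound. Zic5 had 48 counts in the control and 0 in KO replicate 2, at least 10.1-fold lower, and Sox11 had 15 and 0, at least 3.17-fold lower. The formative median lost its sign when the sums were thinned to equal totals (0.08, 7 genes). The core and naive medians were also negative in TE-like cells, at -1.41 and -1.19. There the core median was at percentile 0.08 of the random lists, and the naive median was below all 10000. In the reported setting the lower medians were thus not confined to EPI-like cells. With classes by each cell's marker level the TE-like core and naive medians were 0.39 and 0.14. That class holds other cells, 196 of the control and 77 of KO replicate 2. Of the 77, 46 came from the prolactin cluster and 3 from the EPI-like cluster, as did 5 of the 196. These medians thus do not describe the same cells as the negative ones.

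**Figure D1:**
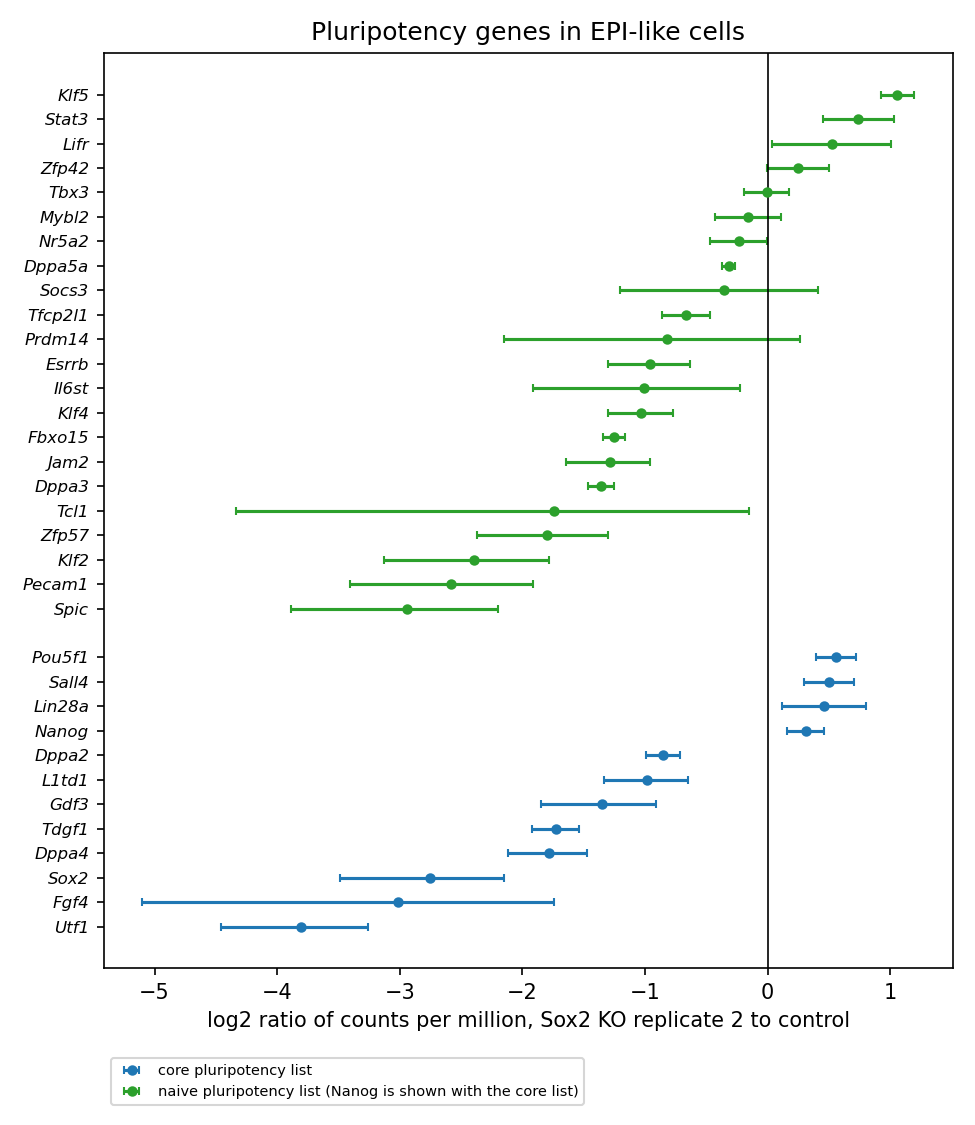
Log2 ratio of KO replicate 2 over control in EPI-like cells (horizontal axis) for each measured gene of the core and naive pluripotency lists, with 95% counting intervals as bars. Utf1 at -3.80, Fgf4 at -3.02 and Spic at -2.94 lie far below 0, and Pou5f1 at 0.56 and Klf5 at 1.06 lie above it.

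Genes of the other early lineages were higher in the EPI-like cells of KO replicate 2. Of 28 trophectoderm genes, 24 were higher, with a median of 1.30, above all 10000 random lists. Keratin Krt19 had 1 and 57 counts, a log2 ratio of 5.92 (3.95 to 11.82), with 14.6 to 32.6 from free RNA. Elf5, a factor of trophoblast stem cells, had 0 and 19 counts, at least 9.99-fold higher, with 5.21 to 11.6 from free RNA. Hand1 was at 3.31 with 34 counts, of which free RNA would give 17.4 at its lowest share, and 38.7, more than all of them, at its highest. Cdx2, the trophectoderm factor, was at 1.67 (1.25 to 2.12) with 2.48 to 5.53 of its 138 counts from free RNA. Of 26 primitive endoderm genes, 21 were higher, with a median of 1.07, above all 10000 random lists. Dkk1, a secreted WNT inhibitor, had 3 and 70 counts, a log2 ratio of 4.99 (3.60 to 7.51), and was at 3.24 with at least 1000 genes, 2.48 without doublets and 2.58 in EPI-scoring cells. Foxa2 was at 3.39 (2.15 to 5.21), with 66.7% of its counts in KO replicate 2 from 1 cell. Fst, which binds activin, had 0 and 19 counts, at least 9.99-fold higher, but 89.5% of them came from 1 cell and free RNA would give 2.23 to 4.97. Of 12 basement membrane genes, 9 were higher, with a median of 0.87, among them Sparc at 1.86 and Col4a2 at 1.82, while Agrn, with 42 and 6 counts, was at -2.05. The primitive endoderm median turned to -0.47 without doublets (55 control and 13 KO replicate 2 cells left), with Foxa2 at -2.08 and Col4a2 at -0.01, and the basement membrane median was then 0.15 and Sparc 0.98. In the cells scoring highest for EPI markers, which held 694209 of the 1368157 counts in KO replicate 2, the primitive endoderm median was 0.05. The trophectoderm median was 1.19 there. The scores use markers that are also members of both lists, so lower values can follow in part from the choice of cells. The trophectoderm median was 0.70 without the largest cell of each library.

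FGF/ERK response genes were lower in the EPI-like cells of KO replicate 2, in 13 of 14 cases, with a median of -0.87, below the middle 95% of the random lists. Besides Fgf4, Egr1 was at -2.80 (-6.21 to -1.11) and Spry4, a feedback inhibitor of the pathway, at -2.15 (-4.72 to -0.62), on 2 and 3 counts in KO replicate 2, where free RNA would give 6.95 to 15.5 for Egr1. Cholesterol and lipid synthesis genes were higher in 15 of 16 cases, with a median of 0.98, above all 10000 random lists. The sterol enzyme Cyp51 was at 3.54 (2.32 to 5.36), the desaturase Scd1 at 2.64 (2.23 to 3.09) and squalene epoxidase Sqle at 1.97 (1.30 to 2.72). Of 16 glycolysis genes 11 were higher, with a median of 0.37 (percentile 97.7). Pfkl was at 3.73, Ldha at 2.11 and Tpi1 at 1.98. Oxidative phosphorylation genes had a median of 0.08 with 10 of 17 higher, Cox6c at -0.89 and Atp5a1 at 0.04. G2/M cell cycle genes were lower in 12 of 15 cases, with a median of -0.55, below the middle 95% of the random lists. Cdc20 was at -1.22, Ube2c at -1.20 and Plk1 at -1.08, and 50.2% of the Ube2c counts in KO replicate 2 came from 1 cell. Without doublets the median was -0.95, Cdc20 at -2.14, Ube2c at -2.02 and Plk1 at -1.63, and without the largest cells Ube2c was at -1.94.

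Of 17 polarity and adhesion genes, 14 were higher in the EPI-like cells of KO replicate 2, with a median of 0.21 that lay within the random lists (percentile 86.5). Cgn, a protein of tight junctions, was at 3.51 (2.79 to 4.41) and Dag1, a laminin receptor, at 1.23. Imprinted genes were higher in 10 of 15 cases, with a median of 0.96, above all 10000 random lists. Peg10 had 0 and 170 counts, at least 89.4-fold higher, with 3.97 to 8.84 from free RNA, and Grb10 was at 3.65 (2.66 to 4.99). H19 was at 4.80 with 343 counts, and free RNA would give 263 to 586. With free RNA subtracted from KO replicate 2 alone, which can only lower a ratio, the imprinted median was 0.85 at the lowest share and -0.23 at the highest. It was 0.53 without doublets, 0.34 in EPI-scoring cells and 0.35 with classes by marker level, the last values below the 0.417 that bounds the middle 95% of the random lists in the reported setting. The p53 and apoptosis list had a median of -0.17 (8 of 15 lower), with Pmaip1 at -1.31 and Trp53 at -1.12. WNT targets had 3 measured genes with a median of 0.16, Lgr5 at -0.87 and Axin2 at 0.16. Dissociation stress genes had a median of -0.19 (8 of 13 lower), which was 0.05 in EPI-scoring cells. With free RNA subtracted from KO replicate 2 alone, it was -0.76 at the lowest share and -2.73 (11 of 13 lower) at the highest. Fos was at 1.94 and Hspa1b at -1.87, with 30 and 6 counts in KO replicate 2, where free RNA would give 14.9 to 33.2 for each. Over 13 alternatives the median ranged from -0.31 to 0.30 for WNT targets, -0.17 to 0.14 for oxidative phosphorylation, -1.36 to -0.78 for FGF/ERK response, 0.90 to 1.16 for lipid synthesis and 0.27 to 0.57 for glycolysis. Genes of the early zygote had 2 measured members, Sp110 at -2.63 among them. Cd52 at -0.93 was the only measured blood and immune gene, and Msx2 at 1.58 was 1 of 2 measured genes of the maternal tract.

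Among all genes with at least 50 counts, the largest deficits in the EPI-like cells of KO replicate 2 included Bmp4, which encodes a secreted growth factor, with 88 and 0 counts, at least 18.6-fold lower. Abcb5 with 66 control counts, Cyp2b23 with 57, Ppm1e with 54 and Fthl17c with 53 also had 0 in KO replicate 2, at least 11.2-fold lower each. Rbfaos, Col26a1, Nwd1, Ddit4l and Ptcra had log2 ratios from -5.58 to -4.01. The largest excesses were eGFP, Prl3d1, Prl3d2, Prl7a1, Prl3d3, Psg29, Peg10, Pyy, Atp4a and Krt19. The counts of Prl3d1, Prl3d2, Prl7a1, Prl3d3 and Psg29 did not exceed those expected from free RNA at its highest share. For Prl3d1, Prl3d2 and Prl7a1, which gave the shares, this held by construction. At the lowest share Prl3d1 and Prl3d2 exceeded the expected counts and Prl7a1 did not, again by construction. Prl3d3 exceeded them at that share and Psg29 did not. Of the 280 Pyy counts 65.4% came from 1 cell, and of the 63 Atp4a counts 90.5%. These ratios carry no test, and the bead version differs along with the genotype.

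**Figure D2:**
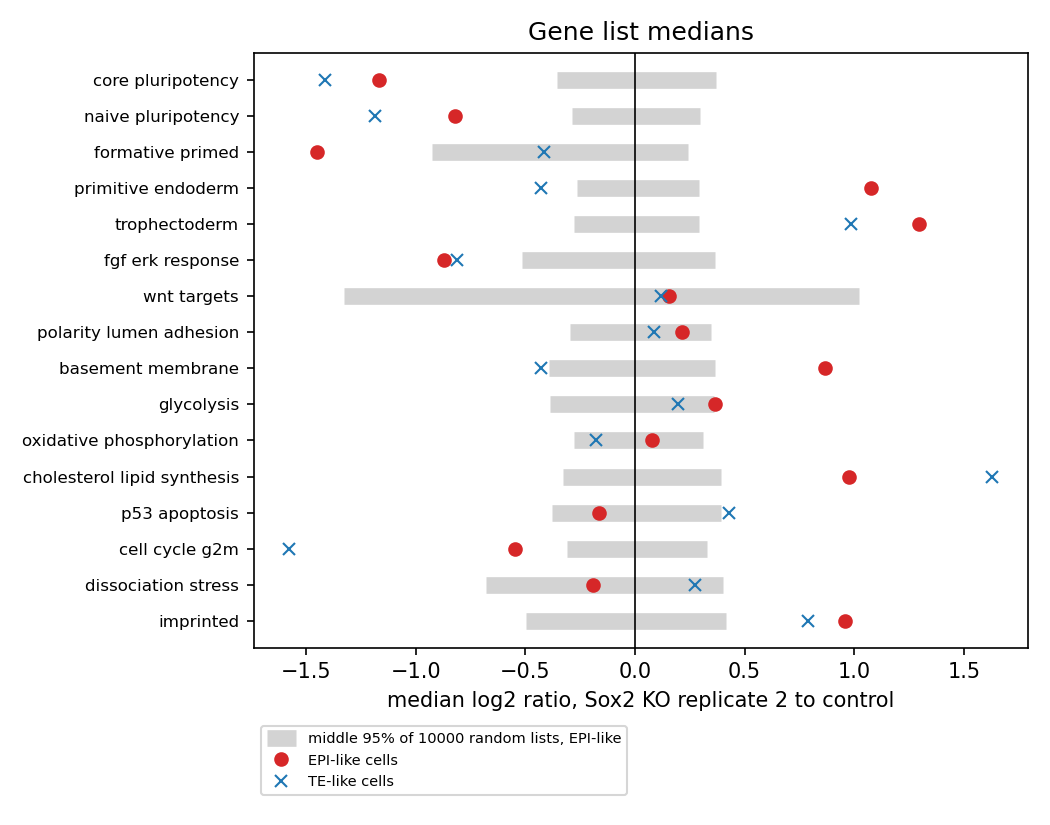
Median log2 ratio of KO replicate 2 over control (horizontal axis) for each gene list, red dots for EPI-like and blue crosses for TE-like cells, with the middle 95% of 10000 random lists for EPI-like cells in grey. In EPI-like cells the core pluripotency median of -1.17 and the naive median of -0.82 lie left of the grey range, and the trophectoderm median of 1.30 and the lipid synthesis median of 0.98 lie right of it. The primitive endoderm median of 1.07 does too, but turned to -0.47 without doublets.

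The same contrast in the trophectoderm used 111 TE-like control cells and 14 of KO replicate 2, with 2436581 and 596446 counts. Trophectoderm genes were higher in 23 of 29 cases, with a median of 0.99, and cholesterol and lipid synthesis genes in 14 of 15, with a median of 1.63, both above all 10000 random lists. Without doublets the lipid median was 0.55. Krt19 had 12 and 159 counts, a log2 ratio of 5.69 (4.90 to 6.72), Elf5 was at 3.51 (3.07 to 3.99) and Lrp2, with 371 and 8 counts, at -3.44 (-4.74 to -2.53), while Insig1 was at 2.58, Sqle at 2.74 and Cyp51 at 2.46. All 15 G2/M genes were lower, with a median of -1.58, among them Cenpf at -4.13, Tpx2 and Plk1 at -2.41. Of 16 naive pluripotency genes 9 were lower, Dppa3 at -4.02 (-4.55 to -3.58) and Lifr, with 46 and 0 counts, at least 3.80-fold lower. Lifr had 3 counts in the 3 TE-like cells of KO replicate 1, 287 CPM (59.2 to 839) against an upper limit of 25.3 CPM in the control. Pou5f1 was at -1.29 (-2.09 to -0.64), Nanog at -1.60, Dppa2 at -2.65 and Dppa4 at -2.10. Imprinted genes had a median of 0.79 (9 of 13 higher), with Phlda2 at 4.48 and Peg10 at 5.08, 90.7% of the latter from 1 cell. FGF/ERK response genes were lower in 8 of 9 cases, but their median of -0.81 lay within the middle 95% of the random lists, with Dusp4 at 68 and 0 counts, Phlda1 at -4.52 and Spry2 at -2.63. The median was -0.43 for primitive endoderm and -0.43 for basement membrane, both within the middle 95% of the random lists. Nid1 was at 2.39 and Nid2 at -3.34. Lama1 was at 3.40 and Cited1 had 25 and 0 counts. The median was 0.43 for p53 and apoptosis (Perp at -1.97, Mdm2 at 1.42), 0.19 for glycolysis (Pfkm at 2.57, Slc2a1 at 2.39, Ldha at 1.06) and -0.18 for oxidative phosphorylation (Cox6c at -0.83, Atp5a1 at -0.18). It was 0.09 for polarity (Ezr at -2.23, Dag1 at 1.42, Ocln at 1.33) and 0.28 for dissociation stress (Junb at 1.45, Ddit3 at 1.21). For formative genes it was -0.41 (Sox4 at -2.07, Tcf15 at -1.89, Dnmt3l at 1.28) and turned in 5 of 13 alternatives. The medians of these lists also lay within the random lists. Over the alternatives the median ranged from -1.78 to 1.4996 for primitive endoderm, -1.79 to 1.58 for basement membrane, -0.76 to 1.91 for dissociation stress, -0.21 to 0.57 for p53 and apoptosis and -0.08 to 0.36 for polarity. It ranged from 0.54 to 2.21 for imprinted genes and 0.52 to 1.17 for trophectoderm, and the G2/M median was negative in all 13. Mybl2 was at -3.06, Kcnq1ot1 at 3.39, Znrf3 at 1.45, Lgr5 at -1.21, Wfdc2 at -0.64 and Msx2 at -0.28, and Sp110 had 45 and 0 counts. S100a8, a granulocyte protein, had 0 and 44 counts, 70.5% of them from 1 cell, S100a9 had 0 and 34, and Hba-a1, a globin, had 43 and 0.

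Gpnmb, a membrane glycoprotein, led the genes lower in TE-like cells of KO replicate 2, with 326 and 0 counts, at least 26.9-fold lower. Ly6e had 470 and 1 counts, a log2 ratio of -6.28 (-12.17 to -4.38). Cfap61 had 148 control counts, Dusp27 99, Snx31 97, Cdc42ep5 and Cfap43 85, Brip1 83, and Vamp9 and Taf9 82, all with 0 in KO replicate 2. Dusp27, however, had 36 counts in the 3 TE-like cells of KO replicate 1, 3447 CPM (2414 to 4772) against 40.9 CPM (33.2 to 49.8) in the control and 132 CPM (66.0 to 237) in barcodes of 1 to 9 counts of KO replicate 1. Lgr5, at 32.6 CPM in the control and 13.3 CPM in KO replicate 2, was 383 CPM (104 to 981) in KO replicate 1. Together with Lifr, these are all the named genes whose level in KO replicate 1 lay beyond the control on the other side, intervals apart, each from 3 cells with 10444 counts in a library with much background. Among the genes higher in TE-like cells of KO replicate 2 were Prl3d1, Prl3d2, Prl7a1 and Prl3d3, with 153, 116, 63 and 53 counts. They did not exceed free RNA at its highest share, by construction for the first 3. At its lowest share free RNA would give 72.7, 51.2, 63 and 48.2 counts, all of those of Prl7a1 by construction. The other genes higher there were Krt19, Olr1 with 0 and 60 counts, Cmklr1 at 5.63, Ctsll3 at 5.61 (72.7% of the control and 69.1% of the KO replicate 2 counts from 1 cell), Igsf8 at 5.32 and Ccdc28a at 5.18. Of the counts in KO replicate 2, 1 cell also held 57.9% for Pou5f1, 55.6% for Nanog, 68.4% for Dppa3, 60.0% for Tpx2, 85.7% for Plk1 and 59.7% for Phlda2. The class joins a cluster of 72 control cells and 12 of KO replicate 2 with a cluster of 39 and 2, so its make-up differs between the libraries. The latter cluster had a median mitochondrial share of 0.0617% in the control and 0.623% in KO replicate 2, against 9.62% and 9.28% in the former, and pseudogenes were among its leading genes. In the larger cluster alone the trophectoderm median was 0.97, the lipid median 1.64 and the G2/M median -1.57. Across 6805 genes measured in both classes, the log2 ratios of EPI-like and TE-like cells had a Pearson r of 0.552 and a Spearman rho of 0.484, where genes are not independent replicates. Of 23 core and naive pluripotency genes with at least 20 counts in TE-like cells, 10 had a lower log2 ratio in EPI-like than in TE-like cells. The difference was -4.41 (-5.68 to -3.14) for Utf1 and -2.82 (-4.25 to -1.39) for Klf2, against 1.85 (1.16 to 2.54) for Pou5f1.

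Over all cells of each library, the single comparison with a test, edgeR called 96 genes higher and 149 lower in KO than control, 245 of 14277. Of these, 239 had 0 counts in KO replicate 1 and 224 had under 50 counts over the 3 libraries. The reporter eGFP was higher in both KO libraries, with 0, 30 and 1634 counts and a log2 fold change of 13.52 (SE 3.48, adjusted p = 0.0130). Gpnmb, with 348, 0 and 0 counts, was lower, with a log2 fold change of -10.47 (SE 3.07, adjusted p = 0.0403). Dnali1, Ankfn1, Cyp2b23, Enox1, Ephx2 and Sap30 were also called lower, with 49 to 59 control counts, 0 in KO replicate 1 and at most 1 in KO replicate 2. A count of 0 in KO replicate 1 allows up to 98.2 CPM (95% Poisson limit), above the control level of each of these genes, Gpnmb at 72.5 CPM included. Sox2 had a log2 fold change of -1.78 (adjusted p = 1.00) and Utf1 one of -2.59 (adjusted p = 0.833), neither past the threshold, and Pou5f1 was at -0.14 and Nanog at -0.43 (both adjusted p = 1.00).

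Of the gene lists, 2 of 13 formative genes passed the threshold in all cells, Sox11 (15, 0 and 0 counts) and Cdh2 (25, 0 and 1), and 3 did adjusted over the list alone. Of 27 primitive endoderm genes 1 passed, Fst (0, 0 and 19 counts, 89.5% from 1 cell), and 2 did adjusted over the list alone. None of the 4 tested blood and immune genes passed and 3 did adjusted over the list alone. In the other 16 lists no gene passed either way, the core and naive pluripotency, trophectoderm, lipid synthesis and imprinted lists among them. The number of calls depended on the software setting: edgeR's bias-adjusted dispersion gave 0 genes (111 at an unadjusted p under 0.05), its robust setting 446, and DESeq2 gave 5. The default made between 60 and 271 false calls on simulated data, so the 245 genes as a set cannot be told from false calls. The reporter eGFP is an exception, since its counting intervals lay far apart. They reached up to 0.77 CPM in the control, and ran from 539 to 1140 CPM in KO replicate 1 and 601 to 662 CPM in KO replicate 2.

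The KO libraries were compared with each other through their log2 ratios against the shared control. Across 14277 genes the Pearson r was 0.20, against a mean of 0.106 (range over 100 simulations 0.0761 to 0.131) for unchanged libraries with a shared control. These simulations drew Poisson counting error only. Any further variation of the lone control enters both ratios and raises r, so a value above this range does not show an effect shared by the KO libraries. Of these genes 7399 had 0 counts in KO replicate 1. Genes are not independent replicates, and the KO libraries also share the bead version that the control lacks.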

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

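The tests in this part were chosen after the result was seen, except the test for neural RNA, whose bound was set before its value was known.

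Prl3d1, a placental lactogen of trophoblast giant cells, was found in barcodes with 1 to 9 counts of KO replicate 2 at 2741 CPM, against 0 in the control library (limit 19.9 CPM), a signal outside the cells that the comparisons use. The same library held a cluster of 46 cells, 39 of them with a Prl3d1 count. Its level of Prl3d1, 19606 CPM, was 7.15 times that of these barcodes, and free RNA as the source of the cluster would need a ratio of at most 1. Embryos of another stage or origin in this library stay open. In the cluster eGFP was 86.2 CPM (63.7 to 114), below the 336 CPM of barcodes with 1 to 9 counts. Those barcodes are the measure of free RNA, which made up at most 10.1% of the counts of the named cells. A level below 336 CPM therefore does not show the reporter absent. TE-like cells of the library were low in eGFP too (43.6 CPM), so the reporter cannot tell cells of another origin from them. The knockout as a biological explanation was not tested, but KO replicate 1, of the same genotype, had 0 Prl3d1 counts in its whole library (upper limit 16.4 CPM) and 0 of 11 cells in this cluster, which allows a share of up to 28.5%, though 3 of its 18 cells with at least 250 genes fell in the matching cluster.

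Pde1c, a phosphodiesterase gene, reached 57496 CPM in barcodes with 1 to 9 counts of KO replicate 1, above the 5811 CPM of the control (upper limit 6168), again outside the comparisons. With Nkain2 and Dlgap1 it took 10.3% of the counts of these barcodes, against 1.07% in the control and 1.76% in KO replicate 2. RNA from neural cells would bring abundant neural mRNAs, but the summed counts of 15 such mRNAs were 0.00652 of those of the 3 genes (56 against 8588). Priming inside long genes may be the source: the 50 leading genes had a median length of 217 kb against 37.7 kb for the others, a ratio of 5.75. A background common to all libraries could not be settled, as rho against the control was 0.34 across 2392 genes, between the bounds set for and against it, with genes taken by their counts in the third library. This set was chosen after genes taken by the compared libraries had given -0.14, and other sets gave 0.29 and 0.08, so the outcome depends on the genes taken.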

How the results depend on the processing

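Chosen after the data had been seen were the bias-adjusted and robust dispersions, the leaving out of the Prl3d1-positive cluster, of mitochondrial genes, of cells not scoring highest for EPI markers and of the largest cells, the subtraction of free RNA at its highest and lowest share, and other cell limits for the Prl3d1-positive share. Also chosen so was the larger TE-like cluster alone. No paired analysis was possible because the single control library shares no embryo, litter or day with either KO library in the labels.

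In EPI-like cells the core median stayed between -1.26 and -1.05 and the naive median between -1.02 and -0.64 over 13 alternatives. The trophectoderm median kept its sign, at 1.68 with at least 1000 genes per cell, 1.10 with classes by marker level, 0.70 without the largest cells, and 0.88 and 1.13 with free RNA subtracted at its highest and lowest share. The primitive endoderm median was -0.47 without doublets, 0.022 with classes by marker level, 0.048 in cells scoring highest for EPI markers and 0.99 with free RNA subtracted at its highest share. Marker levels are not independent of this list, whose members include PrE markers. Leaving out doublets also turned Foxa2 (-2.08), Col4a2 (-0.0059) and Msx2 (-0.31). Msx2 was -0.095 with classes by marker level and -0.10 in EPI-scoring cells. Thinning turned the formative median to 0.078, over 7 genes. Subtracting free RNA at its highest share turned the imprinted median (-0.23), Hand1 (-2.80), Fos (-3.99) and H19 (-4.63), and none of them at its lowest. This held by construction, as the control was left uncorrected and subtraction can only lower a ratio. For the others the cause was not tested. Of the values of single genes under alternatives, 700 stayed within their counting interval, 48 moved and 8 turned. Of list medians, 171 stayed within their interval, 34 moved and 3 turned. Turned means a change of sign where the reported interval left out 0. Counting every change of sign, 12 values of genes and 17 list medians changed, among them oxidative phosphorylation, dissociation stress and WNT targets under several alternatives. The Prl3d1-positive share of 46.9% became 30.3% with at least 1000 genes and 24.4% with no mitochondrial limit.

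In TE-like cells, 160 list medians stayed within their interval over 13 alternatives, 37 moved and 10 turned. The trophectoderm median was 1.17 with at least 1000 genes and 0.52 with classes by marker level. These classes also turned the core (0.39), naive (0.14), formative (0.083) and primitive endoderm (1.4996) medians. In KO replicate 2 they took in the prolactin cells and 3 cells of the EPI-like cluster, so a change of cells goes with these changes. The formative median turned too with at least 1000 genes (0.34), at least 250 genes (0.50), no mitochondrial limit (0.41) and separate clustering (0.21), that of oxidative phosphorylation by thinning (0.010) and that of blood and immune genes with no filter (-0.31). The naive median was -0.19 with no filter, -1.45 with at least 250 genes and -1.40 with no mitochondrial limit. Free RNA subtraction gave -2.06 for core, and -1.78 and -0.92 for primitive endoderm at the highest and lowest share.

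The 245 calls in all cells became 0 with the bias-adjusted dispersion (111 unadjusted), 446 with the robust one, 0 with both (140 unadjusted), 42 with no filter, 5 with DESeq2 (60 unadjusted), 160 with at least 250 genes, 0 with no mitochondrial limit (527 unadjusted), 0 after thinning (29 unadjusted, 1074 genes tested) and 135 without the Prl3d1-positive cluster. They were 166 to 367 with RLE factors, at least 1000 genes, no doublets or no mitochondrial genes. The cause was not tested, except that thinning leaves fewer genes and counts. A count of 0 says nothing about stability where the simulated recovery was 0%.

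The EPI-like share difference of -7.63 points became 14.6 with at least 1000 genes, 17.2 with at least 250 genes and 4.55 with classes by marker level. This came through KO replicate 1 alone, while KO replicate 2, its prolactin cells counted, stayed below the control. In the reported setting the difference ranged from -11.8 to -3.50 when either KO library was left out. Outside the Prl3d1-positive cluster KO replicate 2 lay above the control, at 32.7% against 20.8%. Only with at least 250 genes did each library hold 10 EPI-like cells (112, 13 and 45): edgeR then called 7 genes higher and 0 lower of 11949, its bias-adjusted setting 0 (93 unadjusted) and DESeq2 0 (19 unadjusted). Separate clustering gave no EPI-like value, since KO replicate 1 could not be clustered and the matching cluster of KO replicate 2 was named PrE-like. Without KO replicate 1 the class values are those reported by construction, and without KO replicate 2 1 EPI-like cell is left. Leaving out a KO library leaves 1 library against 1 in all cells, so no test. The 11 cells and 37556 counts of KO replicate 1 set the depth limit.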

Other observations

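The tests for dilution in this part were chosen after the result was seen, as was that for loss of Sox2, while the bounds of the test for a library-wide difference were set before its value was known, without its minimum of 20 counts, which was added before the value was seen, and without a bound on its interval, which was added after.

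The Prl3d1-positive cells of KO replicate 2 carried several genes known from trophoblast giant cells. All 46 scored highest for TE markers. Prl3d1 was 19606 CPM, Prl3d2 12347 CPM, Prl7a1 6463 CPM and Psg29, a pregnancy-specific glycoprotein, 3120 CPM. H19, an imprinted non-coding RNA, was 9570 CPM against 369 CPM in the TE-like cells of the same library, Igf2 was 853 CPM and Hand1, a giant cell factor, 932 CPM. Cdx2, a factor of the early trophectoderm, was 7.03 CPM (1.92 to 18.0) against 144 CPM in TE-like cells. Sox2 had 1 count, Pou5f1 5 and Nanog 7 in these cells.

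The low-depth clusters also differed in content. In KO replicate 2 a cluster of 10 cells with Nanog among its leading genes had eGFP in all 10, at 2040 CPM, Nanog at 754 CPM and Cdx2 at 222 CPM (72.0 to 518, 5 counts). The 34 control cells of this cluster had Nanog at 559 CPM and Sox2 at 164 CPM, and the 10 cells had 0 Sox2 counts, with an upper limit of 164 CPM. In EPI-like cells, Id3, a target of BMP signalling chosen after its values were seen, had 203 counts in the control and 8 in KO replicate 2, a log2 ratio of -3.92 (-5.24 to -3.00), beside the absence of Bmp4 counts there. Gldc, an enzyme of glycine metabolism chosen likewise, was at -3.14 (-3.69 to -2.67).

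The lower pluripotency genes in EPI-like cells of KO replicate 2 were weighed against technical explanations. Dilution would need other RNA to make up 55.5% of that in these cells to give the core median of -1.17, Sox2 included. Genes at least 4-fold higher in the other class gave a median share of 5.33% (2.86 to 14.2, 21 genes) for trophectoderm RNA and 21.0% (15.0 to 24.1, 12 genes) for primitive endoderm RNA. Free RNA made up at most 9.39%, so by this measure none of these alone gave it. The share was the rise over the control divided by the full level in the other class, which is too low for a mixture. Cells scoring highest for EPI markers held 694209 of the 1368157 counts in KO replicate 2. In these cells alone the core median was -1.26. The shares therefore do not exclude dilution. The primitive endoderm level came from the 7 control and 3 KO replicate 2 cells that formed a PrE-like cluster with at least 1000 genes, beside which the core median of EPI-like cells was -1.18. The 3 cells may be among the EPI-like cells of the reported setting, where 3 cells of KO replicate 2 scored highest for PrE markers. The dilution tests replaced earlier ones on the spread among core genes, after their values were seen. A difference between the libraries that acts on all cells alike, such as the bead version, stays open: over 23 core and naive genes with at least 20 counts in TE-like cells the median EPI-like minus TE-like difference was 0.31 (-0.34 to 1.80), above the bound set for it, but genes went both ways (10 of 23 lower), so it decides nothing. The median log2 ratio of these 23 genes was -0.32 in EPI-like and -1.29 in TE-like cells. Loss of Sox2 stays open, since the second KO library held 1 EPI-like cell and genotype and bead version are confounded.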
